A study of Rattus norvegicus with 2 samples.

How the data were processed

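Duodenal mucosa was profiled on 1 rat U34A array for the control and 1 for the immobilized condition. The labels describe 1 rat for each, pooling is not mentioned in the sources used here, and the control and immobilized groups were taken from the sample titles. The deposited values are signal intensity values on a linear scale, 1 per probe set, made by the authors from the array scans. The submitters' processing notes name MAS5, whereas the design text names the manufacturer's software in version 4.0 with its routines for filtering and normalization, so the signal algorithm stays unsettled. That the authors scaled the arrays was seen in the values, as the 2% trimmed mean signal was 215.6 on both. The deposited signals ranged from 0 to 10156 on the control array and to 8294 on the other, with means of 312.0 and 300.6, and the Spearman correlation of the arrays across probe sets, which are not independent replicates, was 0.96. Detection calls were not used here.

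Of the 8799 probe sets, 59 were array controls, 7006 had 1 gene symbol in the array annotation, 308 had several and 1426 had none. The symbols were updated through the gene ID for 6985 probe sets, and 21 kept the array's symbol. Probe sets with several or no symbols entered no gene value. Each gene was represented by its probe set with the highest mean signal, which gave 4736 genes.

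The immobilized rat's array was multiplied by 1.016 so that the median log2 ratio of probe sets above the floor was 0. The floor was then set at the 50th percentile of all signals, 39.9, and ratios were taken on the log2 scale only where both arrays exceeded it. A gene above the floor on 1 array only was given as a bound, its signal over the floor. Genes at least 2-fold higher or lower were counted. A 2-fold difference was 3.23 times the technical SD of 0.31, which was estimated from the differences between probe sets of the same gene. With 1 array per group no test between groups could be made.

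A total of 28 gene lists of pathways and cell types, the rules, and the alternatives were fixed before the data were examined. For each list with at least 5 members above the floor, the median log2 ratio was placed among 10000 random lists of the same size, drawn within 10 classes of mean signal, and called outside if below the 2.5th or above the 97.5th percentile. These percentiles describe this pair of arrays and are not p-values. Further lists of crypt, villus, pancreas and aryl hydrocarbon receptor target genes were added after the data were first examined. Lists shared some members, such as Alpi, Pdia3, Cyp3a9, Cat, Dusp1, Ccl5, Lyz2 and Reg1a.

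The genes named were the 12 highest and 12 lowest log2 ratios, up to 5 per direction with the largest bounds, each calcium transport and vitamin D gene with a probe set, and up to 4 genes per other list farthest from 0. The range over probe sets was given where these differed in sign or by over 1 on the log2 scale, and for some other genes. Alternatives were the signals as deposited, trimmed mean scaling, quantile normalization, loess (span 0.3), floors at the 30th and 70th percentiles, the mean over probe sets, thresholds of 1.5-fold and 3-fold, bounds counted, all probe sets counted, unmatched random lists and the list mean. Counts without exocrine pancreas genes and the calcium list without members of wider function were added after seeing the data.

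The counting was tested on simulated data for the comparison of the immobilized with the control rat (2603 genes). It counted 8% of genes at a true 1.5-fold, 50% at 2-fold, 96% at 3-fold, 100% at 4-fold and 0.04% of 2385 unchanged genes. The simulated noise was the technical SD alone, with no spread between animals. These shares therefore cover array error only and give no rate of false counts between animals. The changed genes were drawn only from genes well above the floor, and the noise was the same at every signal. The shares thus do not hold for genes near the floor. A list shifted by 0.5 stood at percentile 100, and 3 of 40 unshifted lists lay outside the central 95%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.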

Results

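The series compared the duodenum of a rat kept in an immobilization cage for 2 weeks with that of a control rat kept in a metabolic cage over the same 2 weeks. Both animals were male Wistar rats aged 15 weeks, and RNA of the duodenal mucosa from each was hybridised to 1 rat U34A array, an Affymetrix oligonucleotide array. The labels describe a single rat per array, and the sources used here do not say whether RNA was pooled. The labels name the material as epithelial cells. With 1 array per group there was no replicate check, no difference could be set against the spread between animals, and no p-value is given. The number of arrays limits the precision of every value. The array held 8799 probe sets, and the deposited signals had a mean of 312.0 on the control array and 300.6 on the immobilized rat's array. After scaling, 2524 of 4736 genes lay above the signal floor of 39.9 on both arrays, 303 on 1 array only and 1909 on neither. Probe sets of the same gene differed in their log2 ratio with a technical SD of 0.31 (696 genes, 1570 probe sets), which is error within an array and not between animals. The hybridisation spike-ins, RNAs added in known amounts, were lower on the immobilized rat's array for 7 of 9 probe sets above the floor, with a median log2 ratio of -0.21 (range -0.55 to 0.16). The beta-actin probe sets had log2 ratios of -0.35 at the 3' end and -0.50 at the 5' end, and both ends of GAPDH had -0.30.

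Most duodenal genes had similar signals in both rats, and among genes whose probe set carries a single symbol the larger differences included lower signals of antimicrobial lectins and a fatty acid carrier and higher signals of pancreatic enzymes in the immobilized rat. Reg3b and Reg3g, which encode secreted C-type lectins active against bacteria, were 5.25-fold lower (1356 to 258 signal units) and 3.94-fold lower (1284 to 326) on the immobilized rat's array. Cd36, a carrier of long-chain fatty acids, was 3.37-fold lower (718 to 213). Ctrb1, which encodes chymotrypsinogen, was 3.53-fold higher (299 to 1055), and Sycn, which encodes a zymogen granule protein, was 3.51-fold higher. The signal of Cyp1a1, a cytochrome P450 induced by aryl hydrocarbons, was 963 in the control rat and not above the floor in the immobilized rat, at least 24.1-fold lower.

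Across the 2524 genes above the floor on both arrays, 51 were at least 2-fold higher in the immobilized rat (2.02%) and 17 at least 2-fold lower (0.67%). The log2 ratios had an SD of 0.41 over genes, and 2190 genes (86.8%) differed by less than 1.5-fold. Besides Ctrb1 and Sycn, the 12 highest genes held the secretory phospholipase Pla2g2a (3.31-fold), the smooth muscle actin Acta2 (3.20-fold), the sulfotransferase Sult1a1 (3.10-fold), the chemokine Ccl5 (3.10-fold), the fatty acid oxidation enzyme Decr1 (2.92-fold), the cell cycle kinase Cdk4 (2.77-fold), the inducible nitric oxide synthase Nos2 (2.76-fold), the lipase cofactor Clps (2.72-fold), the defensin RatNP-3b (2.72-fold) and the fibrinogen chain Fga (2.70-fold). For Decr1 both probe sets were higher, with log2 ratios of 1.54 and 1.79, as were those of Sycn, with 1.14 and 1.81. A second probe set went the other way for Acta2 (log2 ratio -0.13) and for Nos2 (-0.42). The 12 lowest genes also held the mitochondrial glycerol-3-phosphate dehydrogenase Gpd2 (2.98-fold lower; log2 ratios of -1.58 to -0.63 over 3 probe sets), Serpinb5 (2.64-fold), the splicing regulator Rbfox2 (2.59-fold), the laminin chain Lama3 (2.43-fold), the brush border enzyme Ggt1 (2.29-fold), the kinesin Kif13a (2.28-fold) and C8h11orf54 (2.15-fold). They were completed by the epithelial transport genes Cftr, a chloride channel (2.15-fold lower), and Slc4a4, a sodium bicarbonate cotransporter (2.09-fold lower, 1625 to 778 signal units). In the immobilized rat, Rbfox2 (40.55) and Serpinb5 (41.06) lay just above the floor. Among the highest genes, signals in the control rat were also close to the floor of 39.9 for Sult1a1 (41.4), Nos2 (46.4), Fga (48.6) and RatNP-3b (53.5). Those of Ccl5 (60.1), Pla2g2a (63.4) and Cdk4 (66.9) were not far above it. The ratios of all these genes are limited by their signal over background.

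Some further genes exceeded the floor on 1 array only and have bounds in place of ratios. Besides Cyp1a1, the signals of Kcnj1 (at least 4.95-fold), Manea (at least 2.71-fold), Gja4 (at least 2.53-fold) and Mpp3 (119.9 in the control rat) were lower in the immobilized rat, although another Kcnj1 probe set had a log2 ratio of 0.36. In the other direction, Ptk2b, a tyrosine kinase, was at least 3.48-fold higher, Mapk7 at least 2.79-fold, Capn8 at least 2.73-fold, the lipoxygenase Alox15 at least 2.69-fold and Pde4c at least 2.47-fold. Of the 14 genes at 2-fold with more than 1 probe set above the floor, 4 (Sycn, Decr1, Pex6 and Tmem120a, the last pair named after their values were seen) had all probe sets at 2-fold the same way. In 3 of the 14, namely Acta2, Nos2 and Tpp2 (named after its values were seen), a probe set had the opposite sign.

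**Figure D1:**
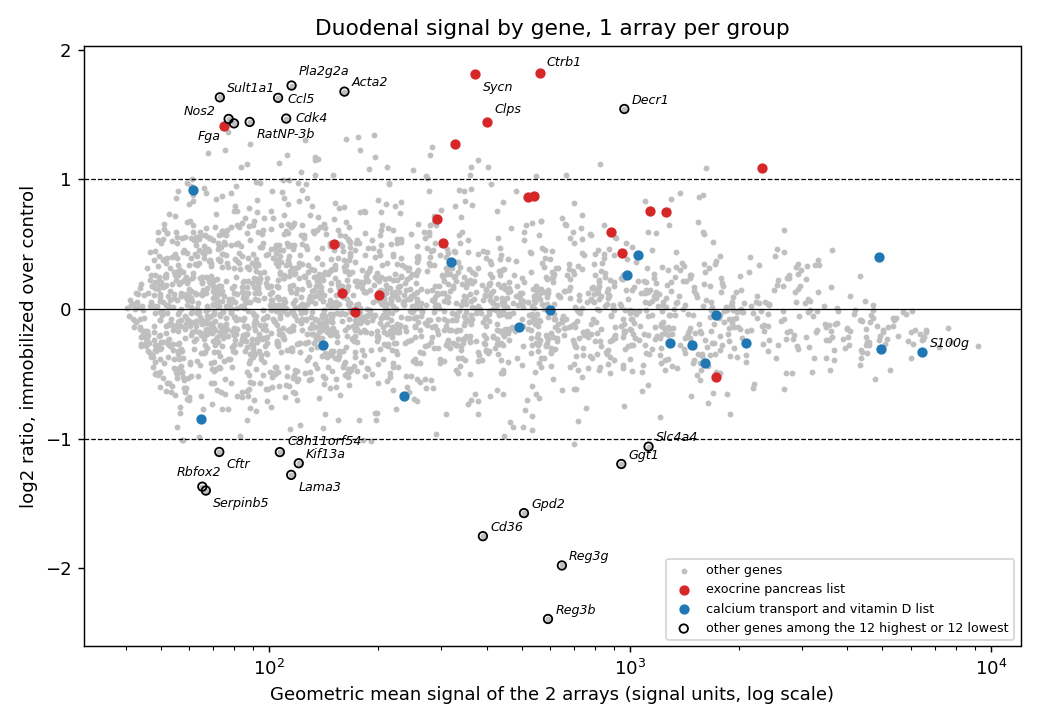
Log2 ratio of the immobilized over the control rat (vertical axis) against the geometric mean signal of the 2 arrays (signal units, log scale) for the 2524 genes above the floor, 1 point per gene, with dashed lines at 2-fold. Exocrine pancreas genes (red) lie mostly above 0 and calcium transport and vitamin D genes (blue) mostly slightly below 0, while Reg3b, Reg3g, Gpd2 and Cd36 lie lowest.

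Immobilization is known for its effect on calcium balance, and the comparison addresses whether genes of duodenal calcium absorption differ. Genes of calcium transport and vitamin D action were slightly lower in the immobilized rat as a group, and none of them differed by 2-fold. S100g, the vitamin D-dependent calcium-binding protein calbindin-D9k of enterocytes and among the brightest genes of these arrays, was 1.26-fold lower (7243 to 5742 signal units). Its log2 ratio of -0.34 (-0.99 at a second probe set) depended on the scaling of bright genes, with -0.10 after quantile normalization and -0.19 after loess. The vitamin D receptor gene Vdr was 1.10-fold lower (517 to 470), and the basolateral calcium pump Atp2b1 was 1.21-fold lower. The sodium-calcium exchanger Slc8a1 was 1.59-fold lower (297 to 187). The partners of the vitamin D receptor differed in direction, with Rxrb 1.80-fold lower and Rxra 1.89-fold higher, both with signals of at most 86.7.

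Of 35 listed genes, 26 had a probe set and 17 were above the floor on both arrays, 12 with a ratio below 0 and 5 above. Log2 ratios lay between -0.42 and -0.26 for Pdia3, the alkaline phosphatase Alpi (-0.19 after quantile normalization or loess), the brush border myosin Myo1a, the tight junction protein Cldn3 and the calcium release channel Itpr3. Second probe sets had 0.26 for Pdia3 and 0.07 for Itpr3. The calcium pumps of the endoplasmic reticulum, Atp2a2 (-0.05) and Atp2a3 (-0.01), hardly differed. The sign of Atp2a3 turned under loess scaling and with the floor at the 30th or 70th percentile. Higher signals were measured for Cyp27a1 (0.26, 0.49 at another probe set), Alpl (0.37), Cyp3a9 (0.40) and Calm2 (0.42). Cyp24a1, the vitamin D 24-hydroxylase, was not above the floor on either array (16.3 and 38.8), like Atp2b2, Atp2b4, Calb1, Casr, Gc, Pth1r and Stc1, and Calb2 was just above it in the immobilized rat only. Trpv6 and Trpv5, the apical calcium channels, were not analysed here. The median log2 ratio of the 17 genes was -0.26, at percentile 0.3 among 10000 random lists matched on signal. It moved to -0.13 (percentile 12.8) after quantile normalization, to -0.13 (18.3) with the floor at the 30th percentile and to -0.10 (21.3) with probe sets averaged, and the mean was -0.09 (18.3). The list stood within the central 95% of random lists under each of these choices. In the same sample the spike-ins were lower, with their median of -0.21, as were 12 of 16 other genes enriched in villus enterocytes, with a median of -0.21 (percentile 3.9), while 10 of 11 crypt-enriched genes were higher, with a median of 0.26 (97.7).

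**Figure D2:**
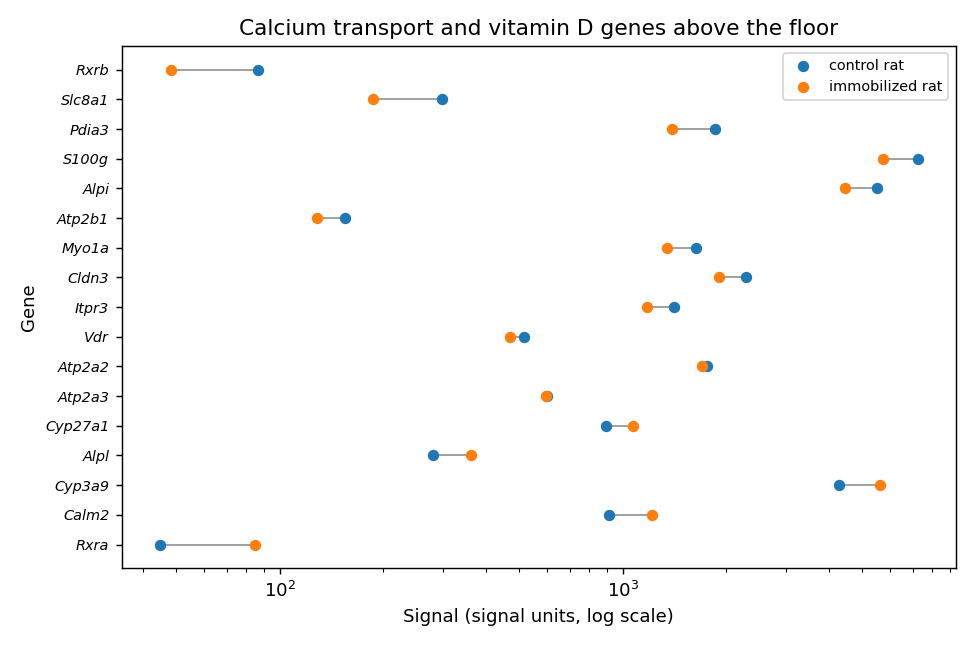
Signal (signal units, log scale) of the 17 calcium transport and vitamin D genes above the floor in the control rat (blue) and the immobilized rat (orange), 1 array each, ordered by log2 ratio. In 12 genes the signal of the immobilized rat lies to the left, among them S100g at 5742 against 7243.

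Genes of the other absorptive functions were more often lower than higher in the immobilized rat, with few differences of 2-fold. Brush border digestive enzymes were lower for 11 of 13 genes, among them Ggt1 (2.29-fold), the aminopeptidase Enpep (1.74-fold) and the metalloprotease Mep1b (1.40-fold), while the trehalase Treh was higher, with a log2 ratio of 0.59. Genes of fat absorption and lipoproteins were lower for 14 of 18, with Cd36 the only one at 2-fold, followed by the acyl-CoA synthetase Acsl1 (1.47-fold, but a log2 ratio of 0.07 at another probe set) and the apolipoproteins Apoa4 (1.25-fold) and Apoa1 (1.22-fold). After quantile normalization the log2 ratios of the last 2 were -0.21 and -0.05. Among nutrient transporters 13 of 21 were lower, including the sodium-proton exchanger Slc9a2 (1.62-fold), the amino acid transporter subunit Slc3a1 (1.40-fold) and the sodium-glucose cotransporter Slc5a1 (1.35-fold, 5048 to 3744 signal units), and the carnitine transporter Slc22a5 was 2.05-fold higher. Iron genes were lower for 6 of 9, with the iron regulatory protein Ireb2 1.88-fold lower, the iron exporter Slc40a1, ferroportin, 1.66-fold lower at -0.73 and -0.74 over its probe sets, Alas1 1.28-fold lower, and the iron importer Slc11a2 at -0.24 (0.21 at another probe set). Other genes enriched in villus enterocytes had a median of -0.21 in the same comparison. In the main setting none of the 4 lists lay outside the central 95% of matched random lists. Their medians and percentiles were -0.22 and 4.5 for brush border enzymes, -0.14 and 15.4 for fat absorption, -0.11 and 17.2 for transporters and -0.09 and 34.2 for iron. Over the 10 settings, list means included, they ranged from -0.31 to -0.19 (percentiles 0.2 to 4.9), from -0.19 to -0.04 (1.8 to 46.6), from -0.16 to -0.04 (7.0 to 35.6) and from -0.28 to -0.08 (2.3 to 36.1). The lower limit was passed by brush border enzymes in 4 of the settings, by fat absorption in 1 (its mean), by iron in 1 (the floor at the 70th percentile) and by transporters in 0.

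In intermediary and drug metabolism, single enzymes differed while the lists as wholes did not stand apart. Of 31 drug and xenobiotic metabolism genes, 14 were higher and 17 lower, with Sult1a1 (3.10-fold), the alcohol dehydrogenase Adh4 (2.34-fold) and the epoxide hydrolase Ephx1 (2.22-fold) at 2-fold higher, and Ephx2 1.97-fold lower although another of its probe sets had a log2 ratio of 0.01. Fatty acid oxidation and ketogenesis genes were higher for 16 of 28, led by Decr1 (2.92-fold), Eci1 (2.01-fold, 0.49 at another probe set), both of which act on unsaturated fatty acids, catalase Cat (1.96-fold, but a log2 ratio of 0.07 at another probe set) and the ketone body enzyme Bdh1 (1.77-fold). Cholesterol and fatty acid synthesis genes divided evenly, 8 higher and 8 lower, with Srebf1 (0.66) and Dhcr7 (0.59, 0.03 at another probe set) above 0 and Me1 (-0.55, from -1.08 to 0.15 over its probe sets) and Insig1 (-0.36, -0.05 at another probe set) below. Respiratory chain genes were lower for 20 of 27, none at 2-fold, with Cox7b at -0.51, Uqcrc2 at -0.49, Atp5pd at -0.36 and Ndufa5 at 0.45. The list medians were -0.01 (percentile 58.0) for drug metabolism, 0.06 (88.4) for fatty acid oxidation, -0.05 (31.6) for cholesterol and fatty acid synthesis and -0.13 (20.4) for the respiratory chain. Over the 10 settings they ranged from -0.08 to 0.08, from 0.04 to 0.14, from -0.10 to 0.03 and from -0.16 to -0.05, inside the central 95% each time.

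Genes of cell division and ribosomal proteins were higher in the immobilized rat together. In the cell cycle and DNA replication list, 17 of 19 genes were higher, 2 of them at 2-fold, Cdk4 (2.77-fold) and the mitotic cyclin Ccnb1 (2.42-fold), followed by the primase subunit Prim1 (1.81-fold) and Racgap1 (1.49-fold), which acts in cytokinesis. Among ribosomal protein genes, 30 of 32 were higher, none at 2-fold, with Rps24 (1.69-fold), Rps10 (1.57-fold), Rpl14 (1.54-fold) and Rpl23 (1.53-fold) highest. The cell cycle median of 0.39 stood at percentile 99.9 and the ribosomal median of 0.27 at percentile 100 of matched random lists, and both lists stayed above the central 95% under each of the 10 settings tried, the main one included. In the same sample the exocrine pancreas list had a median of 0.75 and the crypt-enriched genes outside these lists one of 0.26. Apoptosis and cell stress genes were higher for 11 of 14, including Casp2 (2.04-fold, 0.21 at another probe set), Clu (1.55-fold) and Tnfrsf1a (1.53-fold), with Gadd45a 1.76-fold lower (a log2 ratio of -0.52 at another probe set). Their median of 0.19 stood at percentile 92.5, but was 0.02 (percentile 50.8) with probe sets averaged.

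Immediate early genes, which respond to stimuli within minutes, were lower for 12 of 17, with the transcription factor genes Atf3 (1.82-fold lower) and Junb (1.63-fold lower, but -0.09 on the log2 scale at another probe set) and the phosphatase Dusp1 (1.40-fold lower; -0.95 to -0.25 over 3 probe sets). In the other direction lay Egr1 (1.57-fold higher; 0.40 to 0.71 over 3 probe sets). Their median of -0.21 stood at percentile 1.8, but with the floor at the 70th percentile it was 0.05 (percentile 66.3), a floor that leaves out members under it on either array, such as Atf3 (209 to 115 signal units). Glucocorticoid-responsive genes were lower for 8 of 11, with Nfkbia at -0.57, the receptor gene Nr3c1 at -0.44 (-0.75 at another probe set) and Cebpb at 0.70, and a median of -0.19 (percentile 5.5; -0.22 to -0.10 over the 10 settings). Clock genes were lower for 8 of 9, among them Dbp (-0.71), Nr1d2 (-0.51), Per2 (-0.37) and Bhlhe40 (-0.25), with a median of -0.17 (percentile 11.4; -0.25 to -0.16 over the 10 settings, outside the central 95% only by its mean). The hours at which the tissues were taken are not given in the sources used here. Heat shock and protein folding genes were higher for 14 of 24, with Hspd1 at 0.52 (0.15 at another probe set), and Serpinh1 (-0.64), Pdia4 (-0.52) and Ddit3 (-0.48) below 0, and a median of 0.05 (percentile 84.4; -0.02 to 0.06 over the 10 settings). Genes of oxidative stress defence were higher for 9 of 19, including Cat (0.97), Gpx3 (0.66) and Gpx1 (0.58, 0.25 at another probe set), while Txnrd1 was at -0.61 (-1.29 at another). Their median was -0.03 (percentile 49.2; -0.05 to 0.05 over the 10 settings).

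Marker genes of other cell types set the exocrine pancreas apart from the rest. Of its 20 genes with a probe set, 19 were above the floor on both arrays and Spink1 (named after its values were seen) on neither. Among the 19, 17 were higher in the immobilized rat and 6 of them at 2-fold, with Ctrb1 (3.53-fold), Sycn (3.51-fold), Clps (2.72-fold) and the zymogen granule protein Gp2 (2.66-fold) farthest from 0. The list median of 0.75 stood at percentile 100 and ranged from 0.73 to 0.77 over the settings tried. Among goblet, Paneth and Brunner gland genes the directions divided, with Reg3b and Reg3g lower and Pla2g2a, RatNP-3b and the lysozyme Lyz2 (2.05-fold) higher at 2-fold. Lyz2 is also in the MHC class II and antigen-presenting cell list, and which cells gave these signals was not examined. The goblet, Paneth and Brunner gland list had a median of -0.23 over 10 genes (percentile 4.3). This median was -0.36 (0.1) with the floor at the 70th percentile, -0.13 (19.7) after quantile normalization and -0.12 (14.9) after loess. Enteroendocrine genes had 4 of 9 members higher, with the guanylin gene Guca2a (-0.58), Cck (-0.50) and Chgb (-0.41) below 0 and Tac1 (0.53) above, and their median of -0.16 (percentile 13.5) turned sign under quantile normalization. It ranged from -0.34 (percentile 0.2, with the floor at the 30th percentile) to 0.05 (75.0, after quantile normalization).

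Immune cell markers were more often higher than lower in the immobilized rat, but none of their lists passed the central 95% of random lists in the main setting. Of 6 B, plasma and T cell genes, 5 were higher, with Ccl5 (3.10-fold) and the immunoglobulin chain Iglc1 (2.30-fold) at 2-fold, Cd3g at 0.62 and Cd4 at -0.37. The median of 0.38 stood on the upper limit of the central 95%, which 4 of 10 settings passed, while the median was 0.19 (percentile 87.4) with the floor at the 30th percentile and 0.16 (65.5) at the 70th. Interferon and antigen processing genes were higher for 8 of 13, including Tap1 (0.44, 0.81 at another probe set), RT1-S3 (0.53, but -0.25 at another probe set) and Psmb9 (0.45, but -0.04), with a median of 0.15 (percentile 94.3). It was 0.03 (67.1) with the floor at the 70th percentile, against a mean of 0.25 (98.5). MHC class II and antigen-presenting cell genes were higher for 8 of 12, with C1qb at 0.43 (0.21 at another probe set), C1qc at -0.39 and Cd14 at -0.52, and a median of 0.11 (percentile 92.9) that was 0.02 (72.5) with probe sets averaged. Smooth muscle genes had 4 of 7 members higher, with Acta2, Myh11 (0.59), Actg2 (0.51) and Csrp1 (0.22), and a median of 0.22 (percentile 85.0) that was -0.15 (33.2) with the floor at the 70th percentile, against a mean of 0.40 (97.7). Fibroblast, matrix and endothelial genes had 7 of 15 members higher, among them Vim (0.91), Pdgfra (0.90), Bgn (0.53) and Col3a1 (0.50, 0.12 at another probe set), and a median of -0.01 (percentile 45.0; -0.08 to 0.17 over the 10 settings). Blood and liver genes were lower for 6 of 8, with Hbb (-0.51), Hbb-b1 (-0.33) and Serpina1 (-0.28) against Fga, and a median of -0.13 (percentile 18.4; -0.32 to 0.03 over the 10 settings). Mast cell and granulocyte markers had 3 genes above the floor, Mcpt1 (2.28-fold higher), Cma1 (0.44) and Tpsb2 (-0.31), and enteric neurons and glia had 1, Syn1 (-0.19), too few for a comparison with random lists. Of the 26 lists with at least 5 members, 5 lay outside the central 95%, 3 high (exocrine pancreas, cell cycle, ribosomal proteins) and 2 low (calcium transport and vitamin D, immediate early genes). Lists of genes that vary independently would place 1.3 there. The random lists were drawn gene by gene and make no allowance for genes that vary together between any 2 samples. The excess over 1.3 therefore does not show an effect of immobilization.

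**Figure D3:**
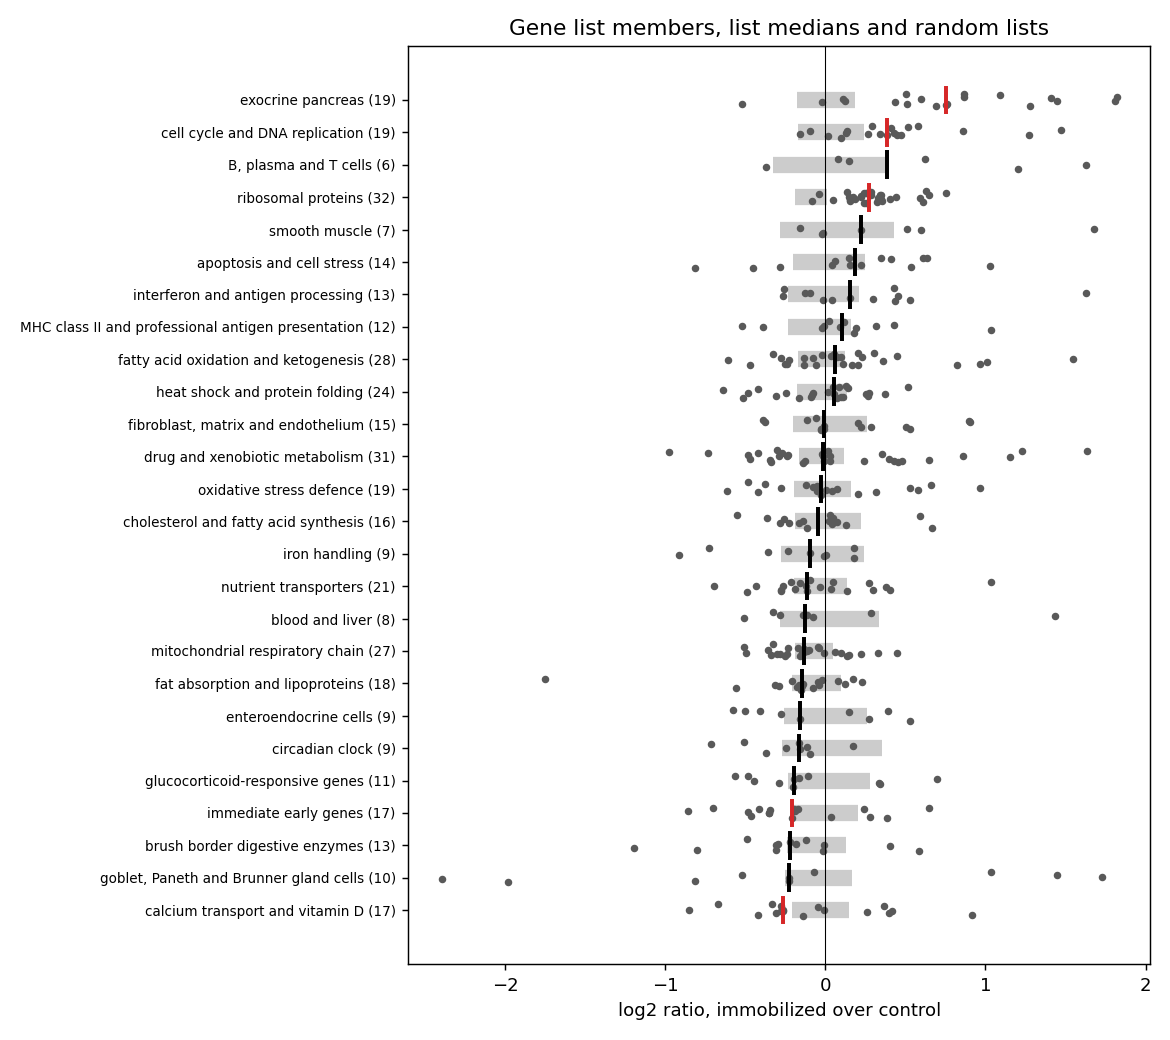
Log2 ratio of the immobilized over the control rat for the members of 26 gene lists (points, 1 gene each; number above the floor in brackets), with the list median (vertical bar, red where outside) and the central 95% of 10000 matched random lists (grey band). The exocrine pancreas list lies highest at a median of 0.75 and the calcium transport and vitamin D list lowest at -0.26.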

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

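Probe sets that carry several gene symbols or none entered no gene value above, and some of them differed strongly between the rats. Among the 704 of them above the floor on both arrays, 32 were at least 2-fold higher in the immobilized rat, 11 with several symbols and 21 with none, and 8 were at least 2-fold lower. Those shares of 4.55% and 1.14% compare with 2.02% and 0.67% of the named genes, a difference that was not tested. The units are unlike, as the first pair counts probe sets and the second counts genes, each by its brightest probe set. The highest of these probe sets had a log2 ratio of 4.46 (110.9 to 2440.0 signal units) and the lowest -1.26. A group of them, with log2 ratios from 1.85 to 4.46, lay above Ctrb1, the highest of the named genes at 1.82. The largest increases on the array are therefore not among the 12 highest genes given above. No biological or technical explanation was tested for them.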

How the results depend on the processing

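The trimmed mean scaling left the deposited signals practically as they were, so it bears on nothing. Both differ from the main setting by little more than a common factor. Counts over the 10 settings thus include settings that are nearly the same. With 51 genes at least 2-fold higher and 17 lower in the main setting, the counts were 110 and 71 with the floor at the 30th percentile and 22 and 9 at the 70th. They were 211 and 123 at 1.5-fold, 6 and 3 at 3-fold, 96 and 35 over all probe sets, and 58 and 26 with bounds counted. These counts follow from the construction, as more or fewer genes or probe sets could pass. The counts were 50 and 20 as deposited, 45 and 20 after quantile normalization, 47 and 18 after loess, 45 and 16 with probe sets averaged and, chosen after seeing the data, 45 and 17 without exocrine pancreas genes. The median of the calcium transport and vitamin D list, -0.26, stayed below 0 in every setting tried, but was -0.132 (percentile 12.78) after quantile normalization, -0.132 (18.34) with the floor at the 30th percentile, -0.104 (21.33) with probe sets averaged and -0.087 (18.31) as a mean, no longer outside the central 95%; the cause was not tested. Without members of wider function, chosen after seeing the data, it was -0.26 (percentile 1.4, 11 genes). By their means 10 lists lay outside, against 5 by their medians. The immediate early gene median turned to 0.048 with the floor at the 70th percentile, which leaves out members under it on either array, such as Atf3. Of the 127 named genes, 127 moved by less than the technical SD under quantile normalization and 126 of 126 measured under loess, where Atp2a3, at -0.01, turned sign. With probe sets averaged, 30 of the 40 named genes that have more than 1 above the floor moved by less and 10 by more. Over 5 of the settings (quantile normalization, loess, both floors, probe sets averaged), 110 of 130 list medians moved by less than 1 SD of random lists and 20 did not, 3 of them of the calcium list. Medians, or means where named, inside the central 95% turned sign for enteroendocrine (quantile), oxidative stress (loess and mean), smooth muscle (floor at the 70th percentile), cholesterol synthesis (floor at the 30th percentile, probe sets averaged) and, as means, drug metabolism, heat shock, fibroblast and blood lists. Lists that passed it only in a single alternative were fat absorption, clock, interferon and smooth muscle (mean), iron and goblet (floor at the 70th percentile) and enteroendocrine (floor at the 30th). No paired analysis was possible because each group has 1 array. For the same reason no array could be left out and no other split of the samples exists. Genes near the floor are limited by their signal over background.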

Other observations

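Genes of the crypt, where intestinal cells divide, and of the mature villus had medians on opposite sides of 0, in lists written before their values were seen, which hold no gene of the lists above. Of 11 crypt-enriched genes above the floor, 10 were higher in the immobilized rat, among them the chloride cotransporter Slc12a2 (log2 ratio 0.83), the nucleolar protein Ncl (0.71) and Hnrnpa1 (0.63). Of 16 villus-enriched genes, 12 were lower, including the monoamine oxidase Maoa (-0.88), Ceacam1 (-0.81), Hsd17b2 (-0.62) and the keratin Krt20 (-0.54, 5728 to 3949 signal units). These examples were chosen after their values were seen.

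The tests of signal-dependent bias for exocrine pancreas genes, of 3 of the other pancreas genes and of aryl hydrocarbon receptor targets were chosen only after the results were seen.

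Exocrine pancreas genes were higher in the immobilized rat, with 17 of 19 above 0. A bias of the arrays that depends on signal is argued against as the whole cause, since the list stood at percentile 100 among random lists matched on signal. The list median of 0.765 after loess added little to that comparison. A candidate explanation is more pancreatic tissue in that sample. Against it, 7 other pancreas genes had a median of -0.18 (percentile 13.0), under a bound set beforehand that would have excluded this explanation. The bound was set aside only after the result was seen. Of these genes, Zg16, with a signal of 6825, is also a goblet cell gene, and Klk1, Pdia2 and Bhlha15 lay near the floor. That filter was uneven, as Gp2, at 45.8 in the control rat, stayed in the main list. The other 3, the insulin genes Ins1 (-0.52) and Ins2 (0.21) and the gene Prss3b (0.81), had a median of 0.21 with a random-list SD of 0.24. The explanation stays open, as so few and mixed genes cannot decide it. The most abundant list genes differed unequally, with Amy2a3 at 1.09, Prss1 at 0.75 and Reg1a, also a goblet and Paneth list gene, at -0.52, and a change within the duodenum was not tested.

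Cell cycle and ribosomal protein genes were higher in the immobilized rat. Signal-dependent bias is argued against as the whole cause. Among random lists matched on signal, the cell cycle list stood at percentile 99.9 and the ribosomal list at 100. The medians after loess, 0.37 for cell cycle and 0.315 for ribosomal protein genes, both above the central 95%, added little to that comparison. A larger share of crypt cells may account for the pattern. The crypt-enriched genes had a median of 0.259 at percentile 97.7, just above the upper limit of the central 95%, 0.255. By the rule used for the other lists they lay outside on the high side, as this explanation requires. So narrow a margin was taken as too small to decide, although the rule was met, and the explanation stays open. Genes such as Ncl and Hnrnpa1 may also rise where cells grow or divide more, so the list cannot tell that from a larger crypt share. Of the same list, Ascl2 and Ephb3 were not above the floor on either array. A smaller share of villus enterocytes stays open as well, with a median of -0.213 at percentile 3.9, short of the limit of 2.5. A response of the duodenum to immobilization was not tested apart from a difference between 2 animals or 2 tissue samples.

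Cyp1a1 was at least 24.1-fold lower in the immobilized rat. A fault of its probe set could not be examined, since only 1 probe set carries the Cyp1a1 symbol alone and 0 others could be compared. Lower activity of the aryl hydrocarbon receptor may be involved, but only 2 other targets lay above the floor on both arrays, Nqo1 (-0.48) and Nfe2l2 (-0.65), with a median of -0.568, too few to decide. Aldh3a1, another target, was at least 2.09-fold lower (83.6 to 35.2 signal units).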
